A study of Mus musculus with 10 samples.

How the data were processed

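Primary mediastinal T cell lymphomas of 10 NPM-ALK transgenic mice were profiled, 5 with intact WASP and 5 WASP-deficient, 1 microarray per mouse. Group and replicate number were taken from the sample titles and genotype labels. The labels call the replicates biological and the series design counts 5 mice per genotype. The p-values of limma for single genes and of the permutation tests thus measure spread between animals. The design text says that WASP-deficient mice of both sexes were used and gives no sex for a single animal.

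The deposited values are probe set intensities that the authors obtained with RMA, per the submitters' processing notes. RMA corrects background, normalizes quantiles over the arrays and summarises probes into probe sets. The software, its version and the genome build and annotation behind it are not given in the sources used here. The deposited intensities ran from 3.309 to 15587.9, a linear scale, although RMA usually returns log2 values and the design fixed in advance had assumed log2. The log2 of each deposited value was therefore taken before any test, and the test itself was kept. Quantile normalization makes arrays alike in their overall distribution, so array-wide differences in RNA amount or quality can no longer be read from these values. Median intensities lay between 116.7 and 122.7 and no pair of columns was identical. The precision is limited by the number of arrays, and 0 columns with values of other samples were left unused.

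Probe sets were named through the platform's annotation table, with symbols checked by gene ID against RefSeq genes of the GRCm38.p6 assembly, used for names only and not for coordinates. Of 34760 probe sets, 22961 were listed there, 21640 with 1 gene symbol and 1321 with several, and 11799 were not named here. Gene IDs matched for 21553 of the 21640, and 0 symbols changed. Probe sets with several symbols or none named no gene. Those of them above the filter, 7099, were tested apart with limma: 0 passed and 269 had an unadjusted p under 0.05.

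Probe sets whose mean over all 10 arrays was under the 40th percentile of all means (log2 6.35, or 81.7 on the linear scale) were left out. Of 13757 remaining probe sets with 1 symbol, the one with the highest mean was kept for each gene, which gave 12670 genes, 678 of them with over 1 probe set. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, WASP-deficient minus WASP-intact with no covariate, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Single values were compared with exact two-sided permutation tests over all assignments of the 10 arrays to groups of 5, which cannot give a p below 0.007937. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

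The 35 gene lists were written before the data were examined, from general knowledge of the pathways, cell types and loci. They hold 830 distinct symbols, of which 755 had a probe set with 1 symbol and 648 were tested. The lists cover actin nucleation, MAPK targets, immediate early genes, ALK and STAT3 targets, immature thymocytes, mature T cells, T cell receptor signalling, cytotoxic and NK cells, regulatory T cells, G1 and S phase, G2 and M phase, Myc and ribosome biogenesis, ribosomal proteins, p53 targets, BCL2 family and apoptosis, interferon response, MHC class I, MHC class II, hypoxia and glycolysis, oxidative phosphorylation, adhesion and migration, B cells, plasma cells, macrophages and monocytes, neutrophils, erythroid cells and platelets, thymic epithelium, endothelium, fibroblasts and stroma, adipocytes, cardiac and skeletal muscle, lung epithelium, genes flanking Was, and sex-linked genes. Another list was tested with them and counted in the adjustment, but is not reported here. The 34 lists with at least 5 tested members were compared with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera sets the genes of a list against the other genes. At the preset correlation its p does not take in how far the genes of a list vary together between animals. A list score is the mean over its tested genes of the log2 level centred on each gene's mean over the 10 arrays.

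The genes named were set by a rule fixed before the data were examined. It took Was, up to 12 genes past the threshold per direction by size, filled up to 8 by smallest p where fewer passed, the 3 members of smallest p in each list with every member past the threshold up to 6, and Cdc42, Rac1, Rac2, Rhoa, Wasl, Wipf1, Dusp6, Stat3, Myc, Tnfrsf8, Cd4, Cd8a, Xist and Ddx3y. Genes outside it were named after their values were seen. These are Eif2s3y, Kdm6a, Eif2s3x, Krt5 and Krt17, named as members past the threshold adjusted over the list alone, Ybx3 and Fmnl2, named as called under another setting, Cd3d, Cd3g, Cd3e and Cd2, and all genes named first in the closing section. Ddx3y was not tested, because the annotation used here pairs no probe set with it.

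The comparison was tested on simulated data with the 12670 genes, 200 of them changed, over 10 runs. Of genes changed by a log2 of 0.5, 32.8% were recovered, of those changed by 1, 79.7%, and of those changed by 2, 93.3%, with 3.79% false calls. A set of 25 genes shifted by 0.3 was called in 10 of 10 runs and an unshifted set in 1 of 10, at an unadjusted camera p under 0.05. Noise was drawn for each gene on its own, so the simulated genes did not vary together as real ones do. The runs therefore cannot show how often camera calls a list by chance in these data. Regrouping the real arrays, described below, gave a median of 7 called lists in the other splits.

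Alternatives fixed before the data were examined were repeated quantile normalization, centring on array medians, no filter or a filter at the 60th percentile, the mean of a gene's probe sets or every probe set on its own, eBayes with trend and robust, array weights, an unmoderated test with unequal variances, the replicate number as a block, the Xist level or a cell type component as covariate, and leaving out each array in turn. The fit without 3 arrays that stand apart and the fit with the first principal component as covariate were chosen after seeing the data. The genotype labels were also regrouped in 100 of the 126 possible splits of the arrays into 5 and 5.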

Results

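Gene expression was measured in primary mediastinal T cell lymphomas of 10 NPM-ALK transgenic mice, with 1 microarray per mouse. NPM-ALK is a fusion kinase that drives anaplastic large cell lymphoma, and WASP, the product of Was, promotes branched actin assembly in blood cells. WASP was intact in 5 mice and deficient in 5. The comparison addressed which transcripts of the lymphoma differ when WASP is missing. Median intensity per array lay between 116.7 and 122.7 on the linear scale, and the number of arrays, 5 per genotype, limited the precision. Levels and differences below are log2 values, given as WASP-deficient minus WASP-intact, with n = 5 arrays per genotype throughout.

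Was fell in the WASP-deficient lymphomas, from 9.22 ± 0.10 to 8.08 ± 0.13 (log2 intensity, SD, n = 5 each). The log2 difference was -1.14 (SE 0.08, limma adjusted p = 0.00088), which left 0.453 of the WASP-intact level. All 5 WASP-deficient arrays, at 7.92 to 8.20, lay below all 5 WASP-intact arrays, at 9.11 to 9.34 (exact two-sided permutation p = 0.007937, the smallest that groups of 5 allow). Was levels thus matched the genotype label on 10 of 10 arrays. Was had a single probe set, and the sources used here do not say whether it lies in the deleted part of the gene. The mean level left in WASP-deficient lymphomas stood at the 66.4th percentile of all probe sets. The call ended under 2 of 24 alternatives, with the Xist level as a covariate (-1.06, SE 0.14, limma adjusted p = 0.376) and with the replicate number as a block (-1.14, SE 0.088, limma adjusted p = 0.136). Over all 24 the adjusted p lay between 0.000377 and 0.376.

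Sex-linked genes separated most arrays by genotype. Xist, the RNA that silences one X chromosome in female cells, was at 11.52, 11.71, 11.90 and 11.85 on WASP-intact arrays 1, 2, 4 and 5 and at 4.40 on WASP-intact array 3. On the 5 WASP-deficient arrays Xist lay between 4.50 and 5.58. The Y-linked histone demethylase genes Kdm5d and Uty went the other way, with Kdm5d at 8.20 to 9.20 on the WASP-deficient arrays and at 8.68 on WASP-intact array 3, against 4.61 to 5.51 on the other 4. Xist and Kdm5d lay on opposite sides of their midpoints on 10 of 10 arrays. The log2 differences were -5.31 for Xist (SE 1.31), 4.02 for Uty (SE 0.90) and 2.96 for Kdm5d (SE 0.66), and none passed over all genes (limma adjusted p = 0.999). Adjusted over the list alone, 6 of 8 tested sex-linked genes passed, which were Uty, Kdm5d, Xist, Eif2s3y, Kdm6a and Eif2s3x. The list as a whole did not pass (camera adjusted p = 0.664), with a mean of 0.56, a median of -0.19 and a test direction that was lower. With the filter at the 60th percentile it passed as lower, with a mean of -1.30 (camera adjusted p = 1.82e-06). That mean can be reached only if the filter removed the Y-linked Uty, Kdm5d and Eif2s3y, whose values were all higher. What passed there was thus the X-linked part of the list. Xist, Uty and Kdm5d passed once WASP-intact array 3 was left out, at -6.78, 5.02 and 3.68. WASP-intact array 3 was the single array on which genotype and these levels went apart.

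**Figure D1:**
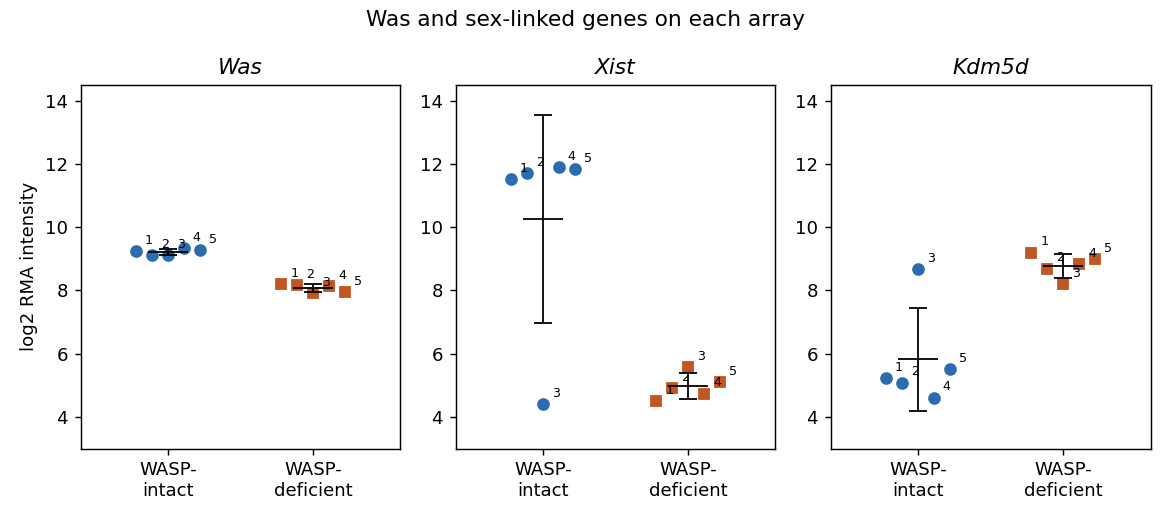
Log2 RMA intensity (vertical axis) of Was, Xist and Kdm5d on each of 5 WASP-intact (circles) and 5 WASP-deficient (squares) arrays, numbered by replicate, with bars for the mean ± SD. Was lies at 9.11 to 9.34 with WASP intact and at 7.92 to 8.20 without it, while WASP-intact array 3 shares the low Xist and high Kdm5d of the WASP-deficient arrays.

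The main variation between lymphomas ran across both genotypes. The first principal component held 60.9% of the variance, and WASP-intact arrays 4 and 5 and WASP-deficient array 1 lay at -51.6, -49.0 and -42.2 on it, against 15.8 to 25.8 for the other 7. Neither this component (exact two-sided permutation p = 0.222) nor the second, with 10.7% of the variance (exact p = 0.429), passed a test of genotype. Over 81% of the variance lay on the first component for 6 of 25 T cell receptor signalling genes, against 1298 of all 12670 genes, and most of the 25 varied less with it. Cd3d and Cd3g, which encode chains of the T cell receptor complex, were at 5.26, 5.60 and 6.47 and at 6.29, 6.97 and 10.24 on those 3 arrays, against 8.96 to 10.08 and 11.45 to 12.23 on the others. Cd2, an adhesion receptor of T cells, was at 11.18, 11.30 and 11.52 on them and between 6.10 and 6.90 on the rest. Cd3e, another chain of the complex, ranged only from 12.06 to 12.59 over all 10 arrays. These sets of arrays were seen in the data and are not groups of the study.

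**Figure D2:**
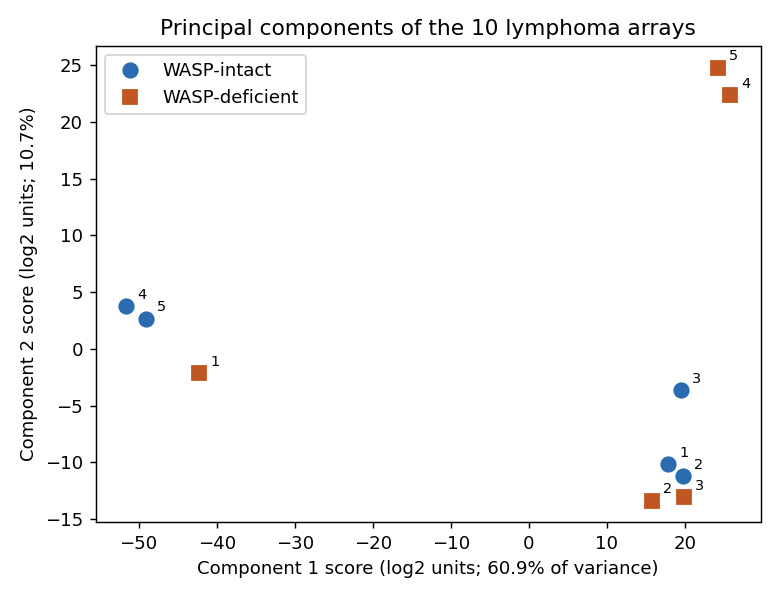
Scores of the 10 arrays on the first and second principal components (log2 units) of the tested genes, with WASP-intact arrays as circles and WASP-deficient arrays as squares, numbered by replicate. WASP-intact arrays 4 and 5 and WASP-deficient array 1 lie between -51.6 and -42.2 on the first component, and the other 7 between 15.8 and 25.8.

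**Figure D3:**
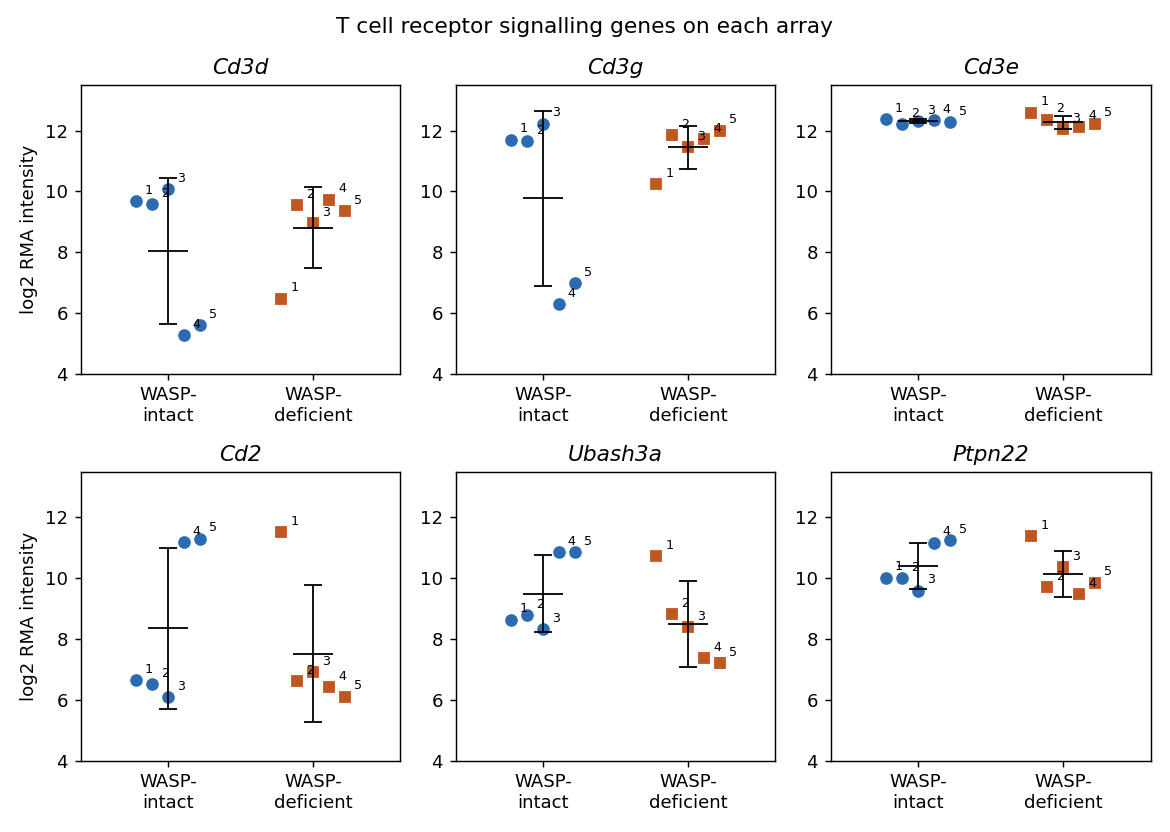
Log2 RMA intensity (vertical axis) of 6 T cell receptor signalling genes on each array, by genotype, numbered by replicate, with bars for the mean ± SD of 5 arrays. Cd3d and Cd3g are low and Cd2 is high on WASP-intact arrays 4 and 5 and WASP-deficient array 1, while Cd3e lies between 12.06 and 12.59 on all 10.

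Across 12670 genes, Was alone passed the test of genotype, so 1 gene was lower and 0 were higher in WASP-deficient lymphomas (limma, adjusted p under 0.05). At an unadjusted p under 0.05 there were 366 genes, 198 higher and 168 lower, where chance alone would give 633.5. That number was 888 without WASP-deficient array 1, 535 with the first component as a covariate (chosen after seeing the data) and 187 with the Xist covariate. A gene that did not pass is therefore not shown to be unchanged. The unmoderated test with unequal variances also called Slc38a7, an amino acid transporter, at 0.45 (SE 0.039 in that test), which limma did not (adjusted p = 0.216). No other gene had a limma adjusted p under 0.99. Among the genes of smallest p, values that did not pass were higher for Lilr4b (0.49), an inhibitory receptor of myeloid cells, Pla2g7 (0.77), a phospholipase secreted by macrophages, Sh3bgrl2 (0.35), Atp4a (0.95), a subunit of the gastric proton pump, and Cldn4 (0.52), a tight junction protein. Values that did not pass were lower for Cthrc1 (-0.62), Adipoq (-1.07), the fat cell hormone adiponectin, Stk26 (-0.69), Nlrc3 (-0.61), Fermt3 (-0.34), an integrin activator of blood cells, and Hp (-1.05), which encodes haptoglobin. Atp4a passed once WASP-deficient array 1 was left out (1.16, limma adjusted p = 0.0371), and without the 3 arrays apart on the first component, a choice made after seeing the data, Ybx3 passed beside Was (2.20, limma adjusted p = 0.0212). An absolute log2 difference of at least 1, whatever its p, was seen for 72 genes, 42 higher and 30 lower.

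No gene close to WASP in function passed the test. Cdc42, the GTPase that activates WASP, differed by -0.04 (SE 0.07), Rac1 by 0.02 (SE 0.11), Rac2 by 0.00 (SE 0.13) and Rhoa by 0.02 (SE 0.06). Wasl, the widely expressed relative of Was, differed by 0.01 (SE 0.10), and Wipf1, which encodes the partner that stabilises WASP, by -0.29 (SE 0.14). Of 33 actin nucleation genes 15 had higher and 18 lower values, 0 passed either over all genes or adjusted over the list alone, and the list did not pass (mean -0.05, camera adjusted p = 0.135). It passed under 1 alternative, without WASP-deficient array 1 (-0.08, camera adjusted p = 0.0423). Its members of smallest p were Dock8 (-0.33), Pstpip1 (-0.23) and Coro1a (-0.41). The 31 adhesion and migration genes did not pass either (mean -0.05, camera adjusted p = 0.196), with Fermt3 at -0.34, Tln1 (talin) at -0.17 and Itgal, a chain of the integrin LFA-1, at -0.60. Nor did 26 genes that flank Was on the X chromosome (mean -0.02, camera adjusted p = 0.652), among them Prickle3 (0.26), Gripap1 (-0.19) and Foxp3 (-0.12).

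No transcript or gene list chosen for its link to ALK signalling passed the test. These values are transcript levels and do not measure kinase activity. Stat3, a transcription factor activated by NPM-ALK, differed by -0.13 (SE 0.08), Myc by -0.02 (SE 0.14), Tnfrsf8, which encodes the lymphoma marker CD30, by -0.49 (SE 0.52), and Dusp6, a phosphatase induced by ERK signalling, by -0.12 (SE 0.29). The 27 ALK and STAT3 target genes had a mean of -0.01 (camera adjusted p = 0.639), with Il2ra at 1.36 (SE 0.69), Junb at -0.26 and Pim3 at 0.19. The 19 MAPK target genes had a mean of 0.08 and a median of -0.008 (camera adjusted p = 0.512), with Spred2 at -0.14, Ier3 at 0.32 and Dusp4 at 0.28. The 17 immediate early genes had a mean of -0.01 (camera adjusted p = 0.498), with Fos at -0.35, Fosb at -0.36 and Atf3 at 0.40. In all 3 lists 0 members passed over all genes or adjusted over the list alone.

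Of 34 gene lists, 9 differed with genotype by camera with a preset correlation of 0.01, 4 higher and 5 lower in WASP-deficient lymphomas. With an estimated correlation 0 of the 34 passed, and with fry 0 passed after adjustment. No member of any list passed over all genes. Of the 9, only the thymic epithelial and adipocyte scores passed an exact two-sided permutation test at 0.05, not adjusted over the 34 lists. That p was 0.103 for macrophages, 0.0952 for MHC class II, 0.246 for hypoxia, 0.183 for muscle, 0.230 for T cell receptor signalling, 0.333 for fibroblasts and 0.564 for G2 and M phase. Of 24 reported lists that did not pass, 11 did so under at least 1 alternative, in either direction, in 25 of 570 values. Regrouping the arrays gave at least 9 lists in 34 of 100 splits, the real one included.

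Thymic epithelial genes were higher in WASP-deficient lymphomas, by a mean of 0.47 over 16 genes, 13 with higher and 3 with lower values (camera adjusted p = 5.97e-08). The call was lost with an estimated correlation (adjusted p = 0.200) and with fry (adjusted p = 0.242). Adjusted over the list alone, 5 members passed and all 5 were higher. These were the tight junction gene Cldn4 (0.52, SE 0.12) and the keratin genes Krt8 (1.06, SE 0.28), Krt14 (0.70, SE 0.23), Krt5 (1.31) and Krt17 (1.14). No other member of the list passed, and which epithelium these keratin and tight junction transcripts came from was not tested. The list score was 0.24 ± 0.20 against -0.24 ± 0.23 (SD, n = 5 each, unadjusted exact two-sided permutation p = 0.0159).

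Adipocyte genes were lower, by a mean of -0.56 over 12 genes, 10 with lower and 2 with higher values (camera adjusted p = 2.50e-08). This call too was lost with an estimated correlation (adjusted p = 0.223) and with fry (adjusted p = 0.250). The mean was -0.33 without the 3 arrays apart on the first component (exact permutation p = 0.200) and -0.37 with the Xist covariate, and the list passed camera at the preset correlation in both. Adjusted over the list alone, 3 members passed, which were Adipoq (-1.07, SE 0.23), the lipid droplet gene Cidec (-0.66, SE 0.19) and the fatty acid carrier Fabp4 (-0.33, SE 0.10). The list score was -0.28 ± 0.29 against 0.28 ± 0.37 (SD, n = 5 each, unadjusted exact two-sided permutation p = 0.0317). Its highest values, 0.78 and 0.55, were those of WASP-intact arrays 4 and 5.

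Macrophage and monocyte genes were higher, by a mean of 0.25 over 18 genes, 17 of them with higher values (camera adjusted p = 2.54e-07, and adjusted p = 0.462 with an estimated correlation). The list score did not pass between the genotypes (exact two-sided permutation p = 0.103). The members of smallest p were the Fc receptor gene Fcgr3 (0.60, SE 0.16) and the lysosomal protease genes Ctss (0.70, SE 0.21) and Lgmn (0.46, SE 0.14), and 0 passed adjusted over the list alone. WASP-deficient array 5 had the lowest score of all arrays, -0.33. Genes of antigen presentation by MHC class II were higher by a mean of 0.26 over 15 genes, 12 with higher values (camera adjusted p = 0.00352, and adjusted p = 0.462 with an estimated correlation). H2-Ab1 was at 0.53, the dendritic cell integrin Itgax at 0.32 and Fscn1 at 0.80, and 0 passed adjusted over the list alone. This call ended without the filter on dim probe sets (0.20, camera adjusted p = 0.0651) and with the Xist covariate (0.03, camera adjusted p = 0.969). It also ended with the cell type component as covariate (0.17, camera adjusted p = 0.0516) and without the 3 arrays apart on the first component (0.13, camera adjusted p = 0.153).

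Hypoxia and glycolysis genes were higher by a mean of 0.23 over 25 genes, 22 with higher values (camera adjusted p = 0.000374, and adjusted p = 0.560 with an estimated correlation). The lactate exporter Slc16a3 was at 0.69, the vasodilator peptide gene Adm at 0.43 and the glycolytic Pgam1 at 0.27, and 0 passed adjusted over the list alone. A single array, WASP-deficient 4, had a list score of 0.72, against -0.31 to 0.23 on the other 9. Without it the mean was 0.08 and the list did not pass (camera adjusted p = 0.276). It also ended with the Xist covariate (-0.08, camera adjusted p = 0.445) and the cell type component (0.09, camera adjusted p = 0.108).

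Muscle genes were lower by a mean of -0.49 over 12 genes, all 12 with lower values (camera adjusted p = 0.00145, and adjusted p = 0.462 with an estimated correlation). The members of smallest p were Nppa (-0.18), Actc1 (-0.39) and Myh7 (-0.39), and 0 passed adjusted over the list alone. The list score was 1.91 on WASP-intact array 4 and lay between -0.32 and 0.02 on the other 9. Without that array the mean was -0.08 and the list did not pass (camera adjusted p = 0.204). The call also ended with array weights (-0.15, camera adjusted p = 0.193), the Xist covariate (-0.02, 0.937) and the first component as covariate (-0.30, 0.0596). With the cell type component the mean was 0.18 (camera adjusted p = 0.147), and without the 3 arrays apart on the first component it was -0.007 (camera adjusted p = 0.919). Fibroblast and stroma genes were lower by a mean of -0.21 over 21 genes, 17 with lower values (camera adjusted p = 0.0248, and adjusted p = 0.611 with an estimated correlation). Acta2, a smooth muscle actin, was at 0.83, Mgp at -0.38 and the collagen gene Col3a1 at -0.57, and 0 passed adjusted over the list alone. The call ended without WASP-intact array 4 or 5 or WASP-deficient array 2, 4 or 5, where the mean lay between -0.20 and -0.10 (camera adjusted p of 0.0550 to 0.287), and was strongest without WASP-intact array 2 (-0.35, 7.07e-06). It ended as well with the Xist covariate (-0.10, camera adjusted p = 0.551), with the first component as covariate (-0.06, 0.201) and without the 3 arrays apart on it (-0.03, 0.736). The mean turned positive with array weights (0.04, camera adjusted p = 0.705) and with the cell type component (0.07, 0.488).

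T cell receptor signalling genes were lower by a mean of -0.20 over 25 genes, 20 with lower values (camera adjusted p = 0.00715, and adjusted p = 0.462 with an estimated correlation). The adaptor genes Skap1 and Lat were at -0.61 and -0.16 and the transcription factor Nfatc1 at -0.15, and 0 passed adjusted over the list alone. The list score was 0.27, 0.28 and 0.41 on the 3 arrays apart on the first component, against -0.43 to 0.02 on the other 7. The call ended without WASP-intact array 4 (-0.16, camera adjusted p = 0.0727) or WASP-deficient array 4 (-0.12, camera adjusted p = 0.104). It also ended with array weights (-0.13, camera adjusted p = 0.127), the Xist covariate (-0.08, 0.405), the cell type component (-0.02, 0.862) and the first component (-0.09, 0.0855). Without the 3 arrays apart on that component it stayed (-0.21, camera adjusted p = 0.00411). Genes of the G2 and M phases were lower by a mean of -0.09 over 29 genes, 25 with lower values (camera adjusted p = 0.0381, and adjusted p = 0.826 with an estimated correlation). Cenpf was at -0.31, the proliferation marker Mki67 at -0.20 and Top2a at -0.18, and 0 passed adjusted over the list alone. This call ended when any of WASP-intact 1, 3 or 5 or WASP-deficient 3, 4 or 5 was left out, with means of -0.08 to 0.009 (camera adjusted p of 0.117 to 0.540). It was stronger without WASP-deficient array 2 (-0.16, camera adjusted p = 2.525e-05) or without the 3 arrays apart on the first component (-0.17, 6.65e-05). It ended too with the filter at the 60th percentile (-0.09, camera adjusted p = 0.0549), array weights (-0.03, 0.443), the cell type component (-0.06, 0.506) and the first component (-0.04, 0.434).

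**Figure D4:**
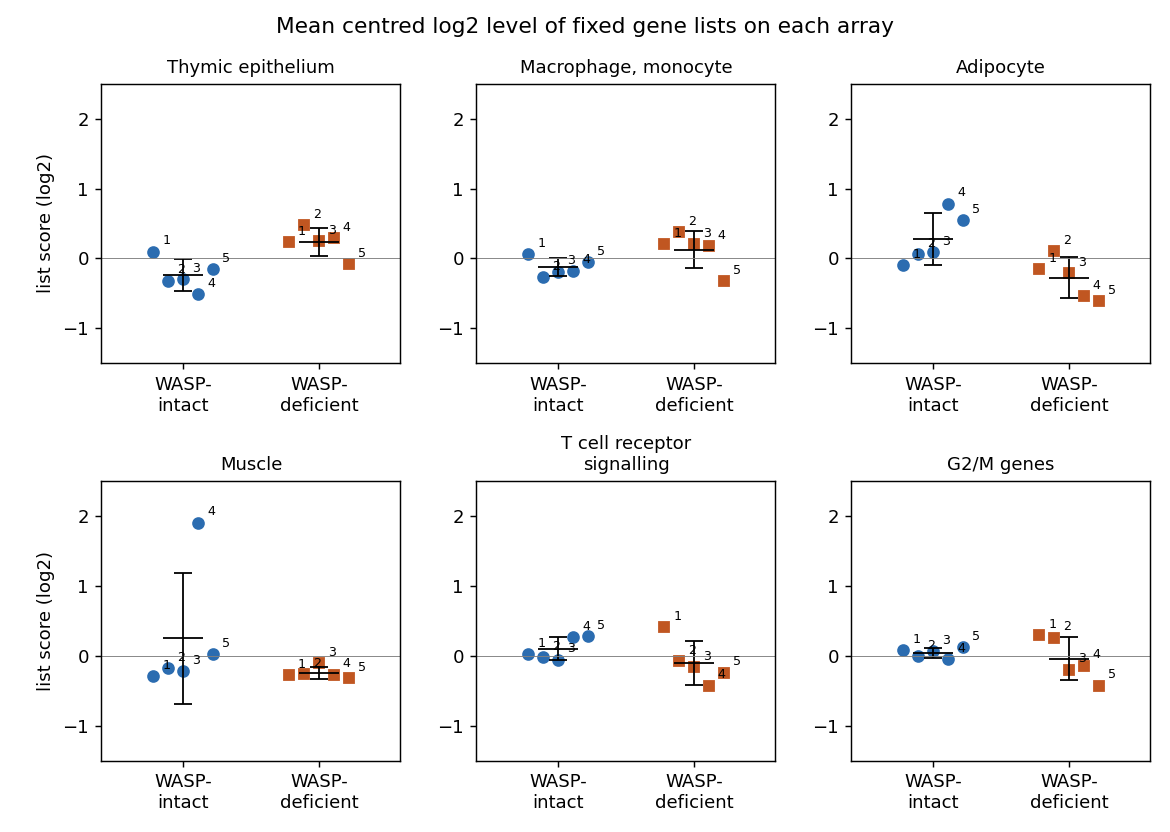
List score (vertical axis, mean centred log2 level of the list's genes) of 6 fixed gene lists on each array, by genotype, numbered by replicate, with bars for the mean ± SD of 5 arrays. The muscle score is 1.91 on WASP-intact array 4 alone, and the thymic epithelial score averages 0.24 in WASP-deficient and -0.24 in WASP-intact lymphomas.

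Lists of T cell state did not pass as reported. Cd4 and Cd8a, the co-receptors of T cell subsets, differed by -0.19 (SE 0.38) and -0.52 (SE 0.73). The 22 immature thymocyte genes had a mean of -0.002 (camera adjusted p = 0.273), with the template-independent polymerase gene Dntt at -0.37, Notch1 at -0.20 and its target Hes1 at 0.52. The 18 mature T cell genes had a mean of -0.16 although the test direction was higher (camera adjusted p = 0.885), with Il2rb at 0.44, Klf2 at 0.31 and the costimulatory receptor Cd28 at -1.40 (SE 1.10). It passed as higher with the Xist covariate (0.29, camera adjusted p = 0.0415) and the cell type component (0.27, 0.0416). The 12 regulatory T cell genes had a mean of 0.12 (camera adjusted p = 0.504), with Tnfrsf9 at 0.45, Il2ra at 1.36 and Gpr83 at 0.69. This list passed as higher with the Xist covariate (0.50, camera adjusted p = 0.00658), the cell type component (0.38, 0.00351) or the first component (0.28, 0.0105), and without the 3 arrays apart on it (0.23, 0.0187). The 8 cytotoxic and NK cell genes had a mean of -0.19 (camera adjusted p = 0.571), with Ctsw at -0.49, Il2rb at 0.44 and Nkg7 at -0.98. In these lists 0 members passed over all genes or adjusted over the list alone.

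Growth, survival and immune response lists did not pass as reported, and 0 of their members passed over all genes or adjusted over the list alone. The 28 genes of the G1 and S phases had a mean of 0.04 (camera adjusted p = 0.155), with Mcm3 at 0.17, Gins2 at 0.20 and Cdca7 at -0.46. They passed as lower with the Xist covariate (-0.20, camera adjusted p = 1.38e-05) and as higher with the replicate block (0.04, 0.0449) and without WASP-intact array 3 (0.11, 0.000944) or WASP-deficient array 4 (0.08, 0.0169) or 5 (0.09, 0.00425). The 27 Myc and ribosome biogenesis genes averaged -0.0005 (camera adjusted p = 0.819), with Rrp12 at -0.18, Nop16 at 0.11 and Nop58 at -0.12, and passed as lower with the Xist covariate (-0.09, 0.0135). The 25 ribosomal protein genes had a mean of -0.01 and a median of 0.003 (camera adjusted p = 0.885), with Rpl12 at -0.29, Rpl27 at 0.13 and Rps9 at -0.20. The 33 oxidative phosphorylation genes averaged -0.02 (camera adjusted p = 0.510), with Ndufs1 at -0.18, Cox7b at -0.10 and Sdhc at 0.12, and passed as lower without WASP-deficient array 4 (-0.06, 0.0272). The 18 p53 targets averaged -0.05 (camera adjusted p = 0.249), with Perp at 0.81, Aen at -0.29 and Trp53inp1 at -0.27. The 19 genes of the BCL2 family and apoptosis averaged -0.05 (camera adjusted p = 0.498), with Bmf at -0.33, Cflar at -0.42 and Apaf1 at -0.13. The 24 interferon response genes had a mean of -0.01 and a median of 0.02 (camera adjusted p = 0.913), with Irf9 at 0.34, Ddx58 at -0.25 and Gbp4 at -0.34. The 11 MHC class I genes had a mean of -0.02 and a median of 0.009 (camera adjusted p = 0.776), with Erap1 at -0.27, Psmb10 at -0.30 and Tap2 at 0.10, and passed as lower with the Xist covariate (-0.18, 0.0353) and without the 3 arrays apart on the first component (-0.14, 0.0282).

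Markers of the remaining cell types did not pass as reported, and 0 of their members passed over all genes or adjusted over the list alone. The 18 endothelial genes had a mean of -0.10 (camera adjusted p = 0.155), with the lymphatic marker Lyve1 at -1.02 (SE 0.30), the VEGF receptor Kdr at -0.28 and Esam at -0.18. They passed as lower without a filter on dim probe sets (-0.10, camera adjusted p = 0.0179) and with the Xist covariate (-0.19, 0.000661). The 6 erythroid and platelet genes had a mean of 0.29 (camera adjusted p = 0.0975), with the platelet chemokine genes Ppbp at 0.72 and Pf4 at 0.73 and the erythroid factor Klf1 at -0.14. They passed as higher under 5 of 23 alternatives, with the replicate block (0.29, camera adjusted p = 0.0389) and the cell type component (0.32, 0.0102), and without WASP-intact array 4 (0.34, 0.00176), WASP-deficient array 2 (0.37, 0.0128) or the 3 arrays apart (0.40, 0.00534). The 7 B cell genes had a mean of 0.16 (camera adjusted p = 0.639), with Ebf1 at -0.31, Blnk at 0.32 and Spib at 0.63. The 9 plasma cell genes had a mean of -0.04 although the test direction was higher (camera adjusted p = 0.776), with Prdm1 at 0.28, Jchain at -0.65 and Ighm at 0.14. The 6 lung epithelial genes had a mean of 0.11 (camera adjusted p = 0.103), with Cyp2f2 at 0.39, Ager at 0.10 and Scgb3a1 at 0.08, and passed as higher with the Xist covariate (0.19, 0.00564). The neutrophil list had 4 tested members of 20, under the minimum of 5, and was not tested.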

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

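The tests on the sex-linked genes and on the 3 arrays that stand apart were chosen after their results were seen. Each value below is the gap between the highest or lowest array of a genotype and the nearest of the other 4, as a share of the whole range of that genotype. Of 314 such groups 26 exceeded the critical value for 5 arrays, where chance would give about 15.7, and 8 of the 26 lay in WASP-deficient array 1.

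WASP-intact array 3 had the lowest Xist of its genotype, at 4.40 against 11.52 to 11.90 (0.95 of the range), and the highest Uty (0.885), Kdm5d (0.779) and sex-linked list score (0.781). A candidate explanation is a different sex ratio of the mice, with WASP-intact array 3 and the WASP-deficient arrays from males and the other 4 from females. Xist and Kdm5d lay on opposite sides of their midpoints on 10 of 10 arrays, as that would need. The design text says that WASP-deficient mice of both sexes were used, whereas all 5 WASP-deficient arrays had low Xist and high Kdm5d, which this explanation leaves unexplained. A swap of array 3 with a WASP-deficient array would need a low Was level there, and Was was at 9.11. Uty split the arrays the same way, at 3.82 to 4.42 on those 4 WASP-intact arrays and at 8.50 to 9.49 on the rest. By these transcripts WASP-intact array 3 and the WASP-deficient arrays look male and the other 4 female. The sex is not given per animal, so it rests on these transcripts alone. Only WASP-intact array 3 parts these levels from genotype, so sex is largely confounded with genotype here.

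WASP-deficient array 1 stood apart on the first principal component, at -42.2 against 15.8 to 25.8 for the other WASP-deficient arrays (0.852), together with WASP-intact arrays 4 and 5. Genotype as the cause is argued against by 4 arrays on the side that the other genotype would take. A lower share of T-lineage cells, if it lowered T cell genes evenly as a set, is argued against as well. The T cell receptor signalling score over all 25 tested members lay above all of the other 7 arrays on 3 of the 3, at 0.27 to 0.41 against -0.43 to 0.02. Along the component 20 members ran higher towards the 3 arrays and 5 lower. Among the 20, Cd2 had 97.9% of its variance on the component and Cd247 0.0414%, and among the 5 Cd3d had 96.1%. The score cannot decide about a lower share where these genes also change on their own. An array-wide difference in intensity or RNA quality could not be decided, since the 3 arrays lay beyond the other 7 on 1 of the measures median and quartiles but quantile normalization makes arrays alike whatever their quality. No other biological explanation was tested, and a different kind of lymphoma on these 3 arrays may be worth a closer look.

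In the same array Cd8a was high, at 10.42 against 7.27 to 8.09 (0.739), Il2rb low, at 6.09 against 6.71 to 6.91 (0.763), and Pstpip1 high, at 9.25 against 8.79 to 8.90 (0.779). Its list scores were the highest of the WASP-deficient arrays for mature T cell genes (0.75), regulatory T cell genes (0.881), plasma cell genes (0.827) and endothelial genes (0.814). The endothelial score was -0.007 against -0.066 to -0.055. WASP-intact arrays 4 and 5 also had high mature T cell scores (0.64 and 0.69, against 0.82 here). Their regulatory T cell scores were 0.28 and 0.31, against 0.56 here, and Il2rb was low on them too (5.67 and 5.88). Their plasma cell scores were 0.18 and 0.13, against 0.86 here. On WASP-intact array 3 Cd8a was low, at 6.38 against values up to 9.52 (0.834).

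On WASP-intact array 4 the muscle list score was 1.91 against -0.29 to 0.02 (0.855), Myh7 was at 7.88 against 6.18 to 6.33 (0.909), Cldn4 was low at 6.84 against 7.23 to 7.30 (0.853) and the erythroid and platelet score was high (0.747). WASP-deficient array 3 had a muscle score of -0.11 against -0.32 to -0.26 (0.734), a low score of genes flanking Was, -0.24 against 0.04 to 0.06 (0.919), and a low Spred2, 9.15 against 9.28 to 9.29 (0.921). The hypoxia score of WASP-deficient array 4 was 0.72 against -0.09 to 0.13 (0.728). WASP-deficient array 5 had a high Dusp6, 11.33 against 9.55 to 10.05 (0.724), a low Krt8, 8.06 against 9.09 to 9.48 (0.724), and a low Nfatc1, 8.93 against 9.11 to 9.18 (0.719). Acta2 was high on WASP-intact array 5, at 10.20 against 9.22 to 9.46 (0.76), and Notch1 on WASP-intact array 2, at 12.62 against 12.55 to 12.57 (0.788).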

How the results depend on the processing

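The fits without the 3 arrays that stand apart and with the first principal component as a covariate were chosen after seeing the data. Was kept its direction under all 24 alternatives, with differences of -1.17 to -1.06, and its side of the threshold under 22. It did not pass with the Xist level as a covariate (-1.06, limma adjusted p = 0.376), and 0 genes passed there, 0 of them lower. Its standard error went from 0.084 to 0.141, the covariate lying close to genotype. The count of genes, 1 lower and 0 higher as reported, was 2 with 1 higher (Slc38a7) in the unmoderated test with unequal variances, 2 with 1 higher (Ybx3) without the 3 arrays that stand apart, and 2 with 1 higher (Fmnl2) with the first principal component as a covariate. Leaving out each array in turn gave 1 to 4 genes, 0 to 2 of them higher and 1 to 2 lower. The 4 were Xist, Uty, Kdm5d and Was, without WASP-intact array 3, and the cause of the other changes was not tested. The count of lists, 9 as reported, was 5 with array weights, 0 with camera at an estimated correlation and 0 with fry, and 7 to 11 when each array was left out. Similar counts hid a change of lists. Of the 9, the Xist covariate kept 4 while 7 other reported lists passed, the cell type component kept 3 with 3 others, the fit without the 3 arrays kept 6 with 3 others, and the first component kept 5 with 1 other. The thymic epithelial, adipocyte and macrophage lists passed under 22 of 24 alternatives each, the exceptions being the estimated correlation and fry. All 22 reuse camera at the preset correlation, whose p does not take in how far a list's genes vary together between animals. They thus do not test the calls against that. The fibroblast list passed under 12 of 24, as did the G2 and M phase list, and the T cell receptor list under 16. The muscle list passed under 15 of 23. Signal over background cannot be read from RMA values, so what dim probe sets could show stays unknown.

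Whether the replicate numbers pair the arrays could not be told from the values. Arrays of the same number deviated from their group means with correlations of -0.714, 0.366, 0.285, -0.406 and -0.373. The negative values belong to numbers 1, 4 and 5, each of which holds 1 of the 3 arrays that stand apart. Those arrays weigh heavily in the correlations, which thus cannot show that a pairing is absent. With the replicate number as a block, 0 genes passed, 0 of them lower, and Was was at -1.14 with a standard error of 0.088 (limma adjusted p = 0.136). The block leaves fewer residual degrees of freedom.

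A change of sign was counted whether or not either value passed. It occurred for 134 of 3602 gene and list values compared, 81 of them outside the fits that leave out 1 array, and in 126 neither value passed. In the other 8, either value passed: fibroblast (array weights, cell type component), muscle (cell type component, without the 3 arrays), MHC class II, hypoxia and G1 and S phase (Xist covariate), and G2 and M phase (without WASP-deficient array 5). For lists the sign is that of the test, which can differ from that of the mean. The cause of these changes was not tested. With the Xist level as a covariate, the gene values were 0.19 for Bmf, 0.041 for Cd28, 1.41 for Cd8a, 0.13 for Cdca7, 0.037 for Ctsw, 0.0069 for Dusp6, -0.13 for Gins2, -0.11 for H2-Ab1, -0.056 for Ighm, 0.043 for Itgal, -0.044 for Mcm3, -0.011 for Pgam1, -0.14 for Rac1 and 0.020 for Stat3. The list means there were 0.040 for adhesion, 0.13 for ALK and STAT3 target, 0.0073 for apoptosis, -0.18 for B cell, -0.20 for G1 and S phase, -0.0027 for cytotoxic, -0.082 for hypoxia, 0.11 for immediate early, 0.032 for MHC class II, 0.067 for sex-linked, 0.14 for immature thymocyte and 0.033 for Was-flanking. With the cell type component as a covariate, the gene values were -0.015 for Ager, 0.22 for Cd28, 0.11 for Cdca7, 0.10 for Cflar, -0.023 for Gins2, 0.049 for Jchain, 0.14 for Myh7, 0.32 for Nkg7, -0.059 for Prdm1, -0.14 for Rac1, -0.022 for Rhoa and 0.30 for Tnfrsf8. The list means there were -0.0054 for actin nucleation, 0.11 for ALK and STAT3 target, 0.18 for muscle, -0.048 for G1 and S phase, 0.12 for cytotoxic, 0.067 for fibroblast, 0.024 for immediate early, 0.023 for interferon, 0.017 for p53 target and 0.54 for sex-linked. With array weights, the gene values were -0.055 for Ager, -0.036 for Prdm1, -0.038 for Rac1, -0.016 for Rac2 and -0.055 for Scgb3a1. The list means there were 0.052 for cytotoxic, 0.038 for fibroblast, 0.12 for interferon, 0.039 for p53 target, 0.011 for plasma cell and 0.0066 for Was-flanking. With the filter at the 60th percentile, the list means were 0.062 for immediate early, -0.00045 for ribosome biogenesis, -0.011 for ribosomal protein and -0.36 for mature T cell. Without a filter on dim probe sets, the list means were 0.037 for B cell, -0.057 for plasma cell and -0.13 for mature T cell. After repeated quantile normalization, the mean of the mature T cell list was -0.15. Without the 3 arrays that stand apart, the gene values were -0.0027 for Gins2, -0.14 for Ighm, -0.077 for Rac1, -0.017 for Rac2 and -0.0069 for Rhoa. The list means there were 0.035 for B cell, -0.0072 for muscle, -0.098 for G1 and S phase, -0.042 for cytotoxic and -0.17 for plasma cell. With the first principal component as a covariate, the value of Rac1 was -0.062. The list means there were 0.071 for ALK and STAT3 target, -0.026 for cytotoxic and 0.014 for interferon.

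Leaving out each array in turn, the gene values that changed sign ranged as follows, in log2: Cd4 -0.41 to 0.061, Dusp6 -0.42 to 0.022, Ighm -0.098 to 0.35, Myc -0.090 to 0.083, Rac1 -0.037 to 0.076, Rac2 -0.056 to 0.081, Rhoa -0.0054 to 0.030 and Wasl -0.028 to 0.071. The list means whose test changed direction ranged over MAPK target -0.0052 to 0.15, ALK and STAT3 target -0.11 to 0.043, mature T cell -0.38 to -0.0074, cytotoxic -0.31 to -0.088, G1 and S phase -0.025 to 0.11, G2 and M phase -0.17 to 0.0092 and ribosome biogenesis -0.049 to 0.025, and over ribosomal protein -0.041 to 0.0047, interferon -0.13 to 0.045, MHC class I -0.072 to 0.021, oxidative phosphorylation -0.061 to 0.020, B cell 0.057 to 0.28, plasma cell -0.26 to 0.030 and Was-flanking -0.041 to 0.036.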

Other observations

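The genes named in this part were chosen after their values were seen, and the tests of the thymic epithelial and adipocyte lists were chosen after those results were seen. The tests by regrouping the arrays were set before. On WASP-intact arrays 4 and 5 and WASP-deficient array 1, many genes stood far from the other 7 arrays. The growth factor gene Igf2 was at 12.22, 12.23 and 12.35 there, against 6.63 to 7.85. The developmental regulator Eya1 was at 12.18, 12.06 and 11.88 against 5.54 to 7.70, and the vesicle trafficking gene Sytl2 at 12.27, 12.15 and 11.70 against 5.35 to 6.58. Il7r, the receptor for a T cell survival cytokine, lay between 10.05 and 10.98 on them and between 6.27 and 7.39 elsewhere, Cd28 between 11.06 and 11.24 and between 6.14 and 8.09, and the adhesion receptor Cd44 between 10.15 and 10.43 and between 7.07 and 8.27. Ptcra, the invariant chain of the pre-T cell receptor, was low, between 7.91 and 9.88 against 10.87 to 11.41. Over 81% of the variance lay on the first component for 1298 genes, 582 higher and 716 lower on these arrays, which are not groups of the study and were not tested against each other.

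On WASP-intact array 4, genes of skeletal muscle contraction and energy supply stood out. Acta1 was at 11.59, Atp2a1 at 11.86, Tnnt3 at 11.12 and Ckm at 10.95, against highest values of 7.19, 7.02, 7.09 and 7.28 on the other 9. The cardiac troponin gene Tnnt2 was at 6.99 there and reached 7.57 on another array. Eif2s3y, a Y-linked translation factor gene, was at 5.96 on WASP-deficient array 2, against 9.25 to 10.32 on the other WASP-deficient arrays, where Kdm5d and Uty showed no such gap.

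Regrouping the arrays bears on both counts. At least 1 gene was called in 3 of 100 splits into 5 and 5, the real one included, with 5 genes in the highest other split. A call was thus rarer than the share of 0.05 set for chance, but the count takes any gene and does not test Was itself. The gene called in the real split is Was, whose loss defines the groups, so the count says nothing about other genes. At least 9 lists were called in 34 of 100 splits, with 15 in the highest other, so chance cannot be excluded for the count of lists.

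Thymic epithelial genes were higher and adipocyte genes lower in WASP-deficient lymphomas, and both lists passed camera at the preset correlation but not at an estimated one (adjusted p = 0.200 and 0.223) or with fry (0.242 and 0.250). A lower share of lymphoma cells might raise the markers of every other cell type alike. The gap between the highest and lowest t over the 11 cell type lists outside the T lineage argues against such an even rise only. It cannot decide about a lower share of lymphoma cells with an uneven mix of other tissues, since such a mix would move the lists apart as well. The gap was 6.10, and 2 of 126 splits of the arrays, each taking its own extremes and the real one included, gave one as large (exact permutation p = 0.01587). A different sex ratio cannot be told apart from genotype here: with Xist as a covariate the differences were 0.50 (95% interval -0.05 to 1.06) and -0.37 (-1.21 to 0.47), and both intervals hold 0, although both lists still passed camera at the preset correlation there (adjusted p = 7.711e-06 and 0.0004389). Without the 3 arrays that stand apart both lists still passed camera at the preset correlation (adjusted p = 5.632e-06 and 0.001055), with differences of 0.41 and -0.33. These arrays stay open as an explanation, since both 95% intervals between arrays, -0.07 to 0.88 and -0.83 to 0.17, hold 0 and the exact permutation p was 0.0857 and 0.200, where the smallest possible is 0.0286. A different amount of thymus and fat tissue around the lymphoma may be a further explanation, and it was not tested.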
